A study of Mus musculus with 8 samples.

How the data were processed

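Polyadenylated RNA was sequenced from the livers of 8-week-old male mice in 4 groups of 2 libraries each: control and liver-specific Med23 knockout (LMKO) mice, either fasted for 24 h or fasted for 24 h and then fed again for 24 h. The series design text gives 2 mice per group, so the spread between the libraries of a group is a spread between animals. Groups were taken from the sample labels.

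Each library came as a list of 23699 annotated loci with a position, a gene symbol and an FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) that the authors computed and deposited. Per the submitters' processing notes, reads were aligned with TopHat 1.4.1 to the mouse build mm9, and transcripts were quantified with Cufflinks 2.0.2 and Cuffdiff 2.0.2. Any scaling between libraries beyond the FPKM unit is not given in the sources used here. The deposited FPKM values were used with no further scaling. FPKM is not a count, so no count model was fitted, and the number of fragments per library is unknown. Low FPKM values of the same locus stood in recurring ratios between libraries, from which a relative depth of 0.956 to 1.112 was read; between 20.8% and 24.2% of the low loci compared sat at the ratio. Depth therefore differed little between libraries as far as this ratio shows. An FPKM listed at 0 can be a failed estimate: Alb, the albumin gene, was listed at 0 in all 8 libraries. Such values are given as listed at 0, with no fold change against them.

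Deposited locus starts count from 0: the difference of end and start equalled a reference gene length for 8691 of 20480 symbols, and that difference plus 1 did so for 528. Starts are therefore printed 1 higher than deposited, on mm9. A reference annotation of another build served only for older gene names and for gene and transcript lengths.

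Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 10865 loci with an FPKM of at least 1 in at least 2 libraries. One linear model held the 4 group means, with 4 residual degrees of freedom, and eBayes with a mean-variance trend added 2.74 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. A log2 fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. The comparisons were LMKO against control in the fasted state, the same in the re-fed state, the mean of both, re-feeding in each genotype, and the difference between the re-feeding responses (the interaction). For each of the genotype comparisons that were set side by side, and for each of the re-feeding comparisons, the calls shared in 1 direction were counted beside the number that independent lists would share; neither pair shared a library.

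Gene lists were tested with camera from limma, which compares the genes of a list with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. There were 27 lists of pathways and complexes and 14 lists of cell type markers, written from general knowledge. The markers of B cells and of pancreatic acinar cells had no measured member. Camera with a correlation estimated from the libraries was an alternative, as was fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. No list call of camera was kept with an estimated correlation, so each list result below rests on the preset value. Members of a list were also counted with p-values adjusted over the list alone.

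The groups, tests, lists and alternatives were fixed before the data were examined, as was the rule for genes named in the text. Med23 was always named. In each comparison, named genes were those with an adjusted p under 0.05, a mean FPKM of at least 5 in the highest of the groups compared and, except for the interaction, no overlap between the libraries of the 2 groups. The 10 largest rises and 10 largest falls were taken, or 8 each for the interaction; where fewer passed, all that passed, and where none passed, the 5 smallest p in each direction as values that did not pass. From each list described, up to 4 members with the smallest p were taken among those with a group mean of at least 1 FPKM. Exceptions are stated where they occur, and some genes that the rule takes are not reported here. Symbols with several loci are named only with that said. Near-identical gene copies, such as the Mup, Mt1 and Mt2, Cyp2c, Cyp4a, Gstm, Selenbp and Raet1 genes, share reads, so the split of reads among their members is uncertain.

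Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, an FPKM of at least 5 in at least 2 libraries, median-ratio scaling, quantile normalization, other eBayes settings (without the trend, and robust), only the 4 libraries of a comparison, a replicate block, summed loci of a symbol, an adjusted p under 0.1, and leaving out each library in turn. With 1 library left out, the remaining library of that group was assumed to vary like the other groups. After the data were seen, fits without loci spanning under 200 bases and fits with a trend on transcript length removed were added.

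The procedure was tested on simulated data for the fasted genotype comparison with 10865 genes. It called 56 of 100 genes changed 2-fold, 89 of 100 changed 4-fold and 6 unchanged genes, not split by FPKM level. For the list test, a simulated re-fed genotype comparison with the ribosomal protein list shifted by 0.5 called that list and 0 of 38 others. Simulated genes varied independently, so this cannot show how often correlated genes would give false list calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.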

Results

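The series measured liver mRNA by sequencing in mice that lack Med23 in the liver (LMKO) and in control mice. Med23 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Livers were taken after 24 h of fasting, or after 24 h of fasting and 24 h of re-feeding, with 2 mice in each of the 4 groups. The deposited FPKM values summed to between 453652 and 597650 per library, and between 10096 and 10403 loci per library had an FPKM of at least 1. Across genes, the correlation of log2(FPKM + 1) between the libraries of a group was 0.963 in fasted controls, 0.967 in fasted LMKO, 0.965 in re-fed controls and 0.977 in re-fed LMKO. Between control and LMKO libraries it lay between 0.944 and 0.963 in the fasted state, where fasted control replicate 2 gave the lowest values (0.944 and 0.947), and between 0.965 and 0.967 in the re-fed state, as high as between the re-fed controls. Between fasted and re-fed libraries it lay between 0.888 and 0.929. The genes are not independent replicates in these correlations.

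Some properties of the libraries moved with feeding or set a library apart. Rn45s, a ribosomal RNA precursor that selection of polyadenylated RNA should remove, ranged from 185 FPKM in fasted LMKO replicate 2 to 3448 FPKM in re-fed control replicate 2. Each gene's deviation in a library from its mean over all libraries was correlated with log2 transcript length, across genes. That correlation was 0.195 to 0.246 in the 4 fasted libraries and -0.307 to -0.268 in 3 re-fed libraries, but -0.014 in re-fed control replicate 1; it compares libraries with each other and does not show how FPKM depends on length within one. The deposited names also carried 2 prefixes, 1 in all fasted and 1 in all re-fed libraries, each with both genotypes. If the prefix marks a batch, that batch cannot be told apart from feeding, whereas the genotype comparisons lie within a prefix.

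The first question was how the deleted gene itself stood in each library. Med23 (chr10, 24589792 to 24633335, mm9) had an FPKM of 2.86 and 2.93 in the fasted controls, 2.35 and 2.18 in fasted LMKO, 2.86 and 2.33 in the re-fed controls, and 1.61 and 1.74 in re-fed LMKO. Each LMKO library thus lay below both control libraries of its feeding state. The mean was 2.90 ± 0.0470 against 2.26 ± 0.122 in the fasted state and 2.60 ± 0.379 against 1.68 ± 0.0940 in the re-fed state (SD, n = 2). The log2 fold change was -0.26 (SE 0.12, limma with Benjamini-Hochberg adjusted p = 0.438) when fasted, -0.42 (SE 0.12, adjusted p = 0.315) when re-fed and -0.34 (SE 0.08, adjusted p = 0.173) over both states, so Med23 did not pass in any of them. Its unadjusted limma p over both states was 0.00486, and over the alternatives the adjusted p of the comparison over both states ran from 0.116 to 0.381. The FPKM covers the whole gene, so exons that remain in the deleted allele and cells other than hepatocytes still count.

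The next question was which genes differed between LMKO and control liver after fasting. The major urinary protein (Mup) genes, which encode pheromone-binding proteins that male liver secretes in large amounts, held the largest falls. Mup7 (chr4, 60079341 to 60083347) went from 2260 ± 540.1 FPKM in controls to 5.36 ± 0.332 in LMKO (SD, n = 2; log2 fold change -8.45, SE 0.29, limma adjusted p = 0.000289). Mup17 (chr4, 61252963 to 61256864) went from 1305 ± 456 to 5.62 ± 5.60 FPKM (-7.90, SE 0.59, limma adjusted p = 0.00558). Mup11 fell by 7.97, Mup14 by 7.52, Mup16 by 6.11 and Mup12 by 5.11 on the log2 scale, with limma adjusted p of 0.00156, 0.00768, 0.000708 and 0.00267. In all, 6 of the 16 tested Mup genes fell. Mup9 (-2.60, limma adjusted p = 0.0541) and Mup20 (-1.99, adjusted p = 0.108) were among those that did not pass. The sum of FPKM over the 23 Mup loci was 15599 and 19793 in the fasted controls and 5097 and 6310 in fasted LMKO.

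Pck1 (chr2, 172978574 to 172984754), which encodes the cytosolic phosphoenolpyruvate carboxykinase that commits carbon to gluconeogenesis, fell from 2186 ± 82.2 to 839 ± 22.3 FPKM in the fasted state (SD, n = 2; log2 fold change -1.38, SE 0.12, limma adjusted p = 0.0133). The call was kept in 4 of the 8 fits that left out a library and was lost without either LMKO library of either feeding state, with a limma adjusted p of up to 0.105 without fasted LMKO replicate 1. It was also lost with no filter on low values (limma adjusted p = 0.0558) and with only the 4 fasted libraries (0.177). Asl (chr5, 130487373 to 130500201), the argininosuccinate lyase of the urea cycle, fell from 879 ± 63.8 to 403 ± 7.19 FPKM (-1.12, SE 0.12, limma adjusted p = 0.0265). Rarres1 (chr3, 67282808 to 67319445), a retinoic acid responder, fell from 59.2 ± 5.94 to 11.2 ± 0.484 FPKM (-2.30, SE 0.16, limma adjusted p = 0.00401). 1300015D01Rik (chr2, 172950250 to 172958705) fell from 18.5 ± 0.585 to 3.79 ± 0.473 FPKM, Tlcd2 (chr11, 75281581 to 75284146) from 35.5 ± 5.97 to 8.16 ± 0.508, and Mycl1, a member of the Myc family, by 1.81 on the log2 scale. Of the 8 fits without a library, Asl was called in 1, that without fasted control replicate 1 (limma adjusted p up to 0.162 in the others). Tlcd2 was called in 5 and lost without fasted control replicate 1 or either fasted LMKO library (limma adjusted p up to 0.148), and Mycl1 was called in 2, those without either re-fed control (up to 0.118 in the others, limma). The 6 Mup genes, Rarres1 and 1300015D01Rik were called in all 8. With only the 4 fasted libraries, Mup11, Mup14, Mup17, 1300015D01Rik, Tlcd2, Mycl1 and Asl were not called (limma adjusted p = 0.0569, 0.143, 0.143, 0.0523, 0.0951, 0.143 and 0.23). With no filter on low values Mup14, Tlcd2, Mycl1 and Asl were lost (limma adjusted p = 0.0553, 0.0917, 0.104 and 0.083), as were Mup14 and Mycl1 with a pseudocount of 0.1 (0.0506 for both), Mycl1 with an FPKM of at least 5 (0.0661) and Asl after quantile normalization (0.0624). Arl4d, Tbc1d30, Ctcfl and Wipi1 also fell, with log2 fold changes of -1.64, -1.40, -1.35 and -1.14; they lay outside the naming rule and were chosen after their values were seen. Of the 8 fits, Tbc1d30 was called in 4 (lost without any LMKO library), Arl4d in 2 (without either fasted control), Wipi1 in 1 (without fasted control replicate 1) and Ctcfl in 0, with limma adjusted p up to 0.14, 0.194, 0.171 and 0.171 in the others.

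The fasted comparison called 18 of 10865 genes, 2 higher and 16 lower, with 1342 genes at an unadjusted limma p under 0.05 and 53 at an adjusted p under 0.1. Both rises were small nucleolar RNA genes. Snora2b (chr15, 98356779 to 98356890) was listed at 0 in all 4 control libraries, at 36.6 and 18.0 FPKM in fasted LMKO and at 18.5 and 35.5 in re-fed LMKO (limma adjusted p = 0.0075 and 0.00848). Snord23 (chr7, 16524111 to 16524209) was listed at 43.1 and 84.8 FPKM in fasted LMKO and at 0 in the other libraries (limma adjusted p = 0.000708). Both span under 200 bases, where an FPKM rests on few fragments. Divided by the ratio of relative depths, the ratio of the 2 values of a group was 2 and 0.5 for Snora2b in fasted and re-fed LMKO and 0.5 for Snord23. Their limma p-values rest on so few fragments that they are given as computed and not read as a difference between genotypes; without loci under 200 bases, an alternative added after seeing the data, 25 genes were called, 5 higher and 20 lower. The fasted Snora2b call was lost with no filter on low values and with only the 4 fasted libraries (limma adjusted p = 0.0542 and 0.0798). The count of 18 became 57 without fasted control replicate 1 and lay between 12 and 57 over the fits that left out a library.

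Of the 39 lists with measured members, 10 were called in the fasted comparison, and 1 of them was higher. Gluconeogenesis genes were lower in LMKO as a list: of 12 measured members Pck1 fell over all genes and 11 did not pass, 7 fell when adjusted over the list alone, and 11 had a lower value (median log2 fold change -0.59, camera adjusted p = 1.34e-09; adjusted p = 0.086 with an estimated correlation). Ppargc1a, the coactivator that drives the fasting program, had means of 6.65 ± 0.0112 and 3.27 ± 0.187 FPKM (-0.84, limma adjusted p = 0.0541). Tat, tyrosine aminotransferase, had 1530 ± 617 and 422 ± 41.5 FPKM (-1.80, limma adjusted p = 0.0851), and Got1, an aspartate aminotransferase, had 484 ± 55.3 and 228 ± 1.26 FPKM (-1.08, limma adjusted p = 0.0926). Fry gave an adjusted p of 0.0062 for this list, and its camera call was kept without each library in turn (adjusted p 9.93e-11 to 1.46e-05).

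Genes of the urea cycle and amino acid breakdown were lower in 17 of 21 members (median -0.39, camera adjusted p = 3.71e-08; adjusted p = 0.358 with an estimated correlation). Asl fell, 20 did not pass, and 5 fell when adjusted over the list alone; Cps1, the entry enzyme of the cycle, had 2057 ± 471 and 917 ± 76.9 FPKM (-1.15, limma adjusted p = 0.145). The median moved to -0.24 without fasted control replicate 2 and to -0.215 without fasted LMKO replicate 1, with the call kept. The FOXO1-linked genes, which insulin represses, were lower in 13 of 18 members (median -0.49, camera adjusted p = 5.83e-06; adjusted p = 0.169 with an estimated correlation). Pck1 fell, 17 did not pass, and 4 fell when adjusted over the list alone. Igfbp1, a binding protein for insulin-like growth factors, had 420 ± 288 and 46.9 ± 34.7 FPKM (-3.16, limma adjusted p = 0.153). Of 17 male-biased liver genes 14 had a lower value and 0 passed limma over all genes, with 9 at an unadjusted p under 0.05, of which 8 were lower, and 4 lower when adjusted over the list alone (median -0.72, camera adjusted p = 1.29e-06; adjusted p = 0.358 with an estimated correlation). Selenbp2, a selenium-binding protein of male liver, had a log2 fold change of -4.43 (limma adjusted p = 0.0541) and Cyp4a12b, a fatty acid hydroxylase, of -2.40 (adjusted p = 0.214).

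Genes of cholesterol synthesis and uptake were lower in 19 of 24 members (median -0.55, camera adjusted p = 0.000129; adjusted p = 0.914 with an estimated correlation), with Dhcr7, the last enzyme of the pathway, at -1.16 (limma adjusted p = 0.228). This call rested on fasted control replicate 1: without it the median was 0.09 (camera adjusted p = 0.972), and without fasted control replicate 2 it was -1.05. Periportal hepatocyte markers (median -0.36, camera adjusted p = 0.000861; adjusted p = 0.639 with an estimated correlation) and heat shock proteins (median -0.19, camera adjusted p = 0.0011; adjusted p = 0.719 with an estimated correlation) were lower as lists, and neither was called without fasted LMKO replicate 1 (camera adjusted p = 0.284 and 0.0825). The periportal list shares Cps1, Ass1, Gls2, Hal and Sds with the urea cycle list. Gluconeogenesis shares Tat and Sds with the urea cycle, and Pck1, G6pc and Ppargc1a with the FOXO1-linked genes. Calls of lists with shared members are not separate results. Sinusoidal endothelial markers were higher in 12 of 12 members, with 0 passing limma and 2 at an unadjusted p under 0.05 (median 0.28, camera adjusted p = 0.0275; adjusted p = 0.914 with an estimated correlation); Kdr, an endothelial receptor of vascular growth factor, was at 0.51 (limma adjusted p = 0.343). The sinusoidal call was lost with an FPKM of at least 5 (camera adjusted p = 0.0639) and without fasted control replicate 1, fasted LMKO replicate 1 or either re-fed control (camera adjusted p = 0.178, 0.0825, 0.0563 and 0.0561). Lipid droplet genes (median -0.20, camera adjusted p = 0.00902) and immediate-early genes (median -0.26, camera adjusted p = 0.0211) were also called, with an adjusted p = 0.639 and 0.824 with an estimated correlation. Neither was called without fasted control replicate 2 (camera adjusted p = 0.131 and 0.66) or fasted LMKO replicate 1 (0.0825 and 0.166). With the length trend removed both were lost (camera adjusted p = 0.0582 and 0.113), and immediate-early genes also after median-ratio scaling and quantile normalization (0.145 and 0.0847).

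The same genotype comparison was made after re-feeding. Mup17 went from 1239 ± 127 to 6.15 ± 0.275 FPKM (SD, n = 2; log2 fold change -7.44, SE 0.59, limma adjusted p = 0.00848) and Mup7 from 1721 ± 171 to 39.0 ± 16.3 (-5.49, SE 0.29, limma adjusted p = 0.00103). Mup11, Mup16 and Mup12 fell by 6.51, 5.67 and 3.88 on the log2 scale (limma adjusted p = 0.00396, 0.00081 and 0.00902). Mup5, a copy outside the near-identical central cluster, fell from 11.6 ± 1.98 to 1.61 ± 0.656 FPKM (-2.29, SE 0.23, limma adjusted p = 0.0266). Mup14 (-5.10) did not pass (limma adjusted p = 0.0699). Pck1 had 374 ± 31.4 and 215 ± 13.5 FPKM (-0.79, SE 0.12) and did not pass (limma adjusted p = 0.168).

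In the re-fed state 11 of 10865 genes were called, 3 higher and 8 lower, with 1269 at an unadjusted limma p under 0.05 and 17 at an adjusted p under 0.1. They included the 6 Mup genes and 4 small RNA genes. Mir1898 (chr15, 12101247 to 12101329) was listed at 285.9 and 309 FPKM in the re-fed controls and at 0 in the other libraries (limma adjusted p = 1.22e-07). Mir5123 (chr4, 40797089 to 40797171) was listed at 276.6 and 265.8 FPKM and Mir215 (chr1, 187137460 to 187137570) at 19.6 and 18.8 in re-fed LMKO, and both at 0 elsewhere (limma adjusted p = 1.22e-07 and 6.53e-06). For these 3 loci the ratio of the 2 values of the group, divided by that of the relative depths, was 1, as equal fragment numbers in both libraries would give. The spread behind their limma p-values is then near 0 whatever the genotype does, so these are given as computed and not read as a difference. Snora2b was the third rise. Without the loci under 200 bases, an alternative added after seeing the data, 7 genes were called. The count was 6 without re-fed control replicate 2 and 5 without re-fed LMKO replicate 2. Mup7 and Mup16 were called in all 8 fits without a library. Mup11 was lost without replicate 2 of either re-fed group (limma adjusted p up to 0.0773), Mup12 also without re-fed LMKO replicate 1 (up to 0.13) and Mup17 without any of the 4 re-fed libraries (up to 0.111). Mup5 was called in 3 of the 8 fits, without either fasted control or re-fed LMKO replicate 1 (limma adjusted p up to 0.165 in the others). Mup5 was also lost after median-ratio scaling, quantile normalization, a pseudocount of 0.1 and an FPKM of at least 5 (limma adjusted p = 0.059, 0.072, 0.0851 and 0.0501). With no filter on low values Mup12, Mup17 and Snora2b (0.0513 each) and Mup5 (0.0982) were not called, and with only the 4 re-fed libraries Mup12 and Mup5 were not (limma adjusted p = 0.0509 and 0.116). Snora2b was lost without either re-fed control or re-fed LMKO replicate 2 (up to 0.0979, limma).

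**Figure D1:**
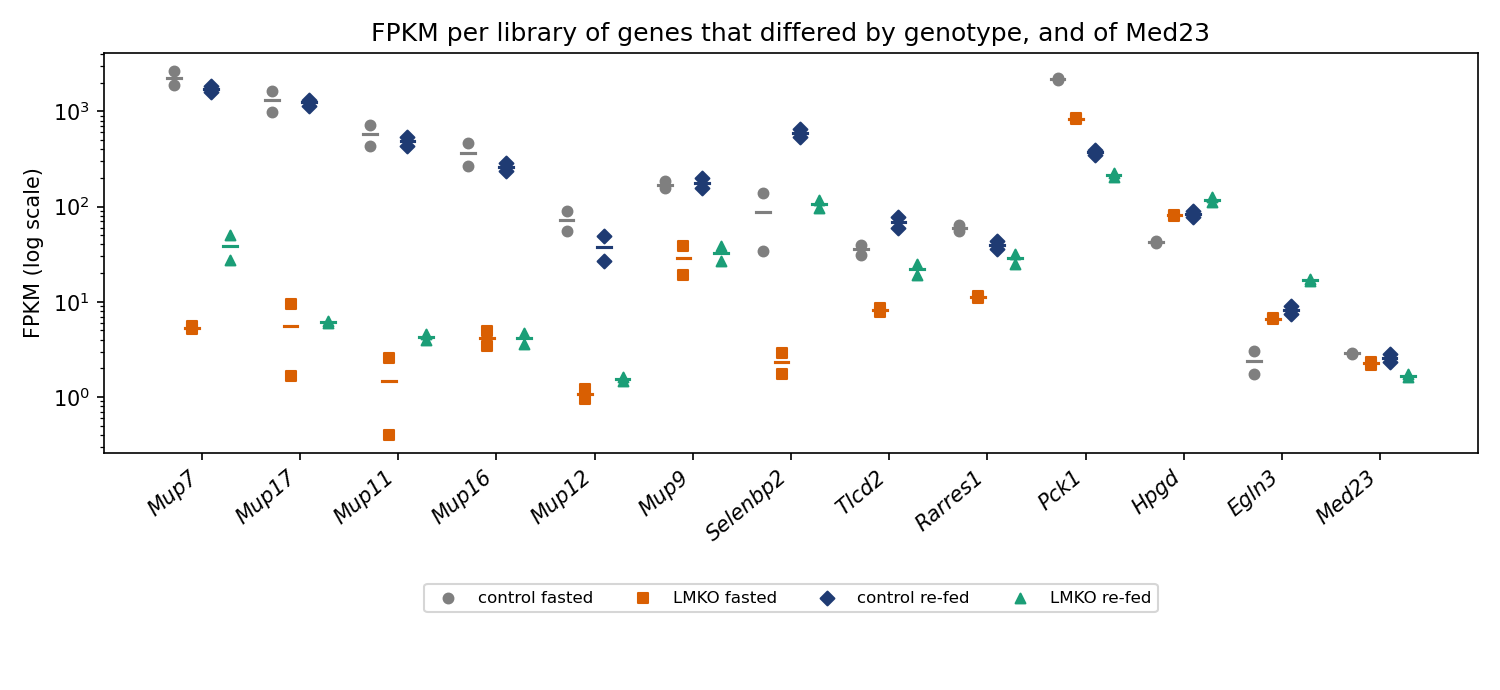
FPKM per library, on a log axis, of Med23, 6 Mup genes and 6 other genes named in the genotype comparisons, in the 4 groups (points, libraries; lines, group means of 2 libraries). Mup7 lies near 2260 FPKM in fasted controls and 5.36 in fasted LMKO, whereas Med23 lies between 1.61 and 2.93 in all libraries.

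Of the 39 lists, 17 were called in the re-fed genotype comparison, though limma called 0 of their 358 members over all genes, with 124 at an unadjusted p under 0.05. Ribosomal protein genes were higher in LMKO in 48 of 48 members, of which 40 rose when adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 1.93e-25; adjusted p = 0.419 with an estimated correlation). Rpl38 had 858 ± 86.8 and 1520 ± 35 FPKM (0.83, SE 0.15, limma adjusted p = 0.206), and Rpl23 had a log2 fold change of 0.61 (adjusted p = 0.239). Oxidative phosphorylation genes were higher in 44 of 45 members, 16 of which rose when adjusted over the list alone (median 0.35, camera adjusted p = 3.84e-16; adjusted p = 0.419 with an estimated correlation). Cox7a2, a small cytochrome oxidase subunit, had means of 189.5 and 349 FPKM (0.87, limma adjusted p = 0.246). Most members of both lists have short transcripts, and re-fed control replicate 1, whose deviations were not related to length as in the other re-fed libraries, stands in this comparison. Without each library in turn the ribosomal median stayed between 0.43 and 0.51, and with the length trend removed it was 0.33. Quantile normalization gave 0.26 with the call kept.

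Chaperones of the endoplasmic reticulum (median 0.30, camera adjusted p = 2.62e-05) and heat shock proteins (0.41, camera adjusted p = 8.69e-05) were higher in re-fed LMKO, in 18 of 20 and 14 of 16 members (adjusted p = 0.419 with an estimated correlation for both). Hspa8, the constitutive cytosolic chaperone, had 727 and 1359 FPKM (0.92, limma adjusted p = 0.246) and Bag3, its co-chaperone, had 16.6 and 27.6 FPKM (0.70, limma adjusted p = 0.184). Over the list alone, 2 chaperone and 3 heat shock genes rose. Without re-fed LMKO replicate 1 the median was 0.18 for the chaperones with the call kept and 0.26 for heat shock proteins with the call lost (camera adjusted p = 0.0602). Proteasome genes were higher in 30 of 31 members (median 0.24, camera adjusted p = 2.3e-05; adjusted p = 0.6 with an estimated correlation), and genes of fatty acid oxidation and ketogenesis in 24 of 25 (0.31, camera adjusted p = 0.000458; adjusted p = 0.481 with an estimated correlation). Bdh1, a ketone body dehydrogenase, was at 0.60. Without re-fed LMKO replicate 2 the medians of these lists were 0.15 and 0.20, both called.

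Genes of fatty acid synthesis were lower in re-fed LMKO in 14 of 18 members (median -0.63, camera adjusted p = 0.00118; adjusted p = 0.419 with an estimated correlation). Fasn, the fatty acid synthase, had 126.8 ± 61.7 and 53.6 ± 3.50 FPKM (-1.14, limma adjusted p = 0.365), and Acss2, which makes acetyl-CoA from acetate, had 165 ± 1.64 and 73.9 ± 5.23 FPKM (-1.15, limma adjusted p = 0.269). The median was -0.21 without re-fed control replicate 1, with the call kept. Cholesterol genes were lower in 22 of 24 members (-0.39, camera adjusted p = 0.0178; adjusted p = 0.775 with an estimated correlation), with Sc5d, a sterol desaturase, at -1.23 (limma adjusted p = 0.315). That call was lost without re-fed control replicate 1 (median -0.19, camera adjusted p = 0.134) and without re-fed LMKO replicate 1 (0.05, camera adjusted p = 0.977), and the median was -0.60 and -0.85 without the other re-fed control and LMKO library. Male-biased genes were lower in 13 of 17 members, 3 of them when adjusted over the list alone (-0.62, camera adjusted p = 0.00295), and periportal markers in 10 of 11, again 3 over the list alone (-0.51, camera adjusted p = 0.000789), with an adjusted p = 0.419 with an estimated correlation for both. Neither was called without re-fed LMKO replicate 2 (camera adjusted p = 0.306 and 0.0563; medians -0.35 and -0.20), and the male-biased median was -0.33 without re-fed control replicate 1. Gluconeogenesis genes (median -0.07, camera adjusted p = 0.446) and FOXO1-linked genes (-0.12, adjusted p = 0.0632) were not called in the re-fed state, but both were after quantile normalization (-0.19 and -0.12, camera adjusted p = 0.0472 and 0.0217).

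Markers of other liver cells moved with the re-fed genotype comparison, beside all of the groups above. Kupffer cell and macrophage markers were lower in 12 of 12 members (median -0.55, camera adjusted p = 3.77e-05), stellate cell markers in 11 of 11 (-0.53, camera adjusted p = 0.000149) and sinusoidal endothelial markers in 11 of 12 (-0.33, camera adjusted p = 0.000499). The adjusted p was 0.419, 0.419 and 0.45 with an estimated correlation. Csf1r, the macrophage growth factor receptor, had 5.45 and 3.26 FPKM (-0.57, limma adjusted p = 0.417), and Col3a1, a collagen of stellate cells, was at -0.67. Cell cycle genes were lower in 12 of 13 members, 3 of them when adjusted over the list alone (-0.55, camera adjusted p = 1.14e-05; adjusted p = 0.419 with an estimated correlation). Without re-fed control replicate 2 the stellate median was -0.22 and the sinusoidal -0.28, both no longer called (camera adjusted p = 0.127 and 0.0751), and the Kupffer median was -0.28 with a camera adjusted p of 0.044. Without re-fed LMKO replicate 2 the sinusoidal median was -0.14 (camera adjusted p = 0.323), and without re-fed LMKO replicate 1 it was -0.52. The cell cycle median was -0.29 without re-fed control replicate 1 and -0.33 without re-fed LMKO replicate 1, called in both. With an FPKM of at least 5 the cell cycle call was lost (median -0.11, camera adjusted p = 0.404), as was the stellate call (-0.33, adjusted p = 0.0995). Interferon-stimulated genes (-0.33, camera adjusted p = 0.000872), clock genes (-0.41, adjusted p = 0.013) and genes of bile acid synthesis and transport (-0.30, adjusted p = 0.0243) were lower as lists, with an adjusted p = 0.6, 0.419 and 0.419 with an estimated correlation. Interferon genes were not called without re-fed control replicate 2 or re-fed LMKO replicate 1 (camera adjusted p = 0.358 and 0.0816), clock genes without replicate 1 of either re-fed group (0.111 and 0.0795), and bile acid genes without replicate 2 of either (0.246 and 0.0847). Over the fits without a library their medians ran from -0.54 to -0.16, from -0.78 to -0.20 and from -0.40 to -0.19.

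Averaged over both feeding states, 34 genes differed between the genotypes, 10 higher and 24 lower, with 1646 at an unadjusted limma p under 0.05 and 117 at an adjusted p under 0.1. Of the rises 4 (Snora2b, Snord23, Mir215 and Mir5123) and of the falls 1 (Mir1898) span under 200 bases, and all but Snora2b were listed at 0 in both genotypes of 1 feeding state. Without such loci 33 genes were called, 7 higher and 26 lower. Of the Mup genes 9 fell, led by Mup17 at -7.67, Mup11 at -7.24 and Mup7 at -6.97 (limma adjusted p = 0.000693, 0.000197 and 3.43e-05). Selenbp2 (chr3, 94497495 to 94508328) fell by 3.45 on the log2 scale (SE 0.41, limma adjusted p = 0.0339), with means of 86.8 and 2.32 FPKM in fasted and 593 and 107 FPKM in re-fed control and LMKO liver. Pck1 fell by 1.09 (SE 0.09, limma adjusted p = 0.00521), Tlcd2 by 1.79 (adjusted p = 0.00521) and Rarres1 by 1.38 (adjusted p = 0.00544), and these 3 were called in all 8 fits without a library. Hpgd, which inactivates prostaglandins, rose from 42.9 ± 1.51 to 80.9 ± 0.937 FPKM in the fasted and from 83.6 ± 9.19 to 118 ± 10.4 FPKM in the re-fed state (0.70, SE 0.09, limma adjusted p = 0.0459). Egln3, an oxygen-sensing prolyl hydroxylase, rose with means of 2.40 and 6.64 FPKM fasted and 8.22 and 17.0 FPKM re-fed (1.08, SE 0.14, limma adjusted p = 0.0447). Inhbc, a liver activin subunit, rose by 0.72 on the log2 scale (limma adjusted p = 0.0473). Hpgd and Inhbc were called in 0 of the 8 fits without a library (limma adjusted p 0.0758 to 0.175 and 0.0771 to 0.163), and Egln3 and Selenbp2 in 2, those without either fasted control (limma adjusted p up to 0.192 and 0.176 in the others). With no filter on low values Hpgd, Inhbc, Egln3 and Selenbp2 were not called (limma adjusted p = 0.0721, 0.0831, 0.107 and 0.104), and after quantile normalization the first 3 were not (0.0602, 0.0769 and 0.0578). Inhbc and Egln3 were lost after median-ratio scaling (limma adjusted p = 0.0767 and 0.0516), Inhbc and Hpgd with the length trend removed (0.0703 and 0.0501), Egln3 with a pseudocount of 0.1 or 0.5 (0.0545 and 0.0514) and Selenbp2 with the robust setting of eBayes (0.0593). The count of 34 was 55 without fasted control replicate 1, and 18, 19 and 18 without fasted LMKO replicate 1, re-fed control replicate 1 and re-fed LMKO replicate 2. The split of higher and lower calls was 8 and 29 with median-ratio scaling and 4 and 22 with quantile normalization.

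Of the 39 lists 16 were called over both states. Lower lists that were called without each library in turn were gluconeogenesis (median -0.38, camera adjusted p = 5.62e-06), male-biased genes (-0.52, adjusted p = 8.25e-07), the urea cycle (-0.23, adjusted p = 3.69e-05), FOXO1-linked genes (-0.34, adjusted p = 4.55e-05) and periportal markers (-0.34, adjusted p = 2.96e-05). With an estimated correlation their adjusted p was 0.242, 0.405, 0.405, 0.26 and 0.405. The higher lists called without each library were ribosomal proteins (0.30, camera adjusted p = 1.59e-14), oxidative phosphorylation (0.22, adjusted p = 3.36e-10) and chaperones of the endoplasmic reticulum (0.26, adjusted p = 4.08e-05), with adjusted p = 0.515, 0.405 and 0.515 with an estimated correlation. Over all genes Pck1, Sox9 and Selenbp2 were the called members of these lists, and Sox9, a transcription factor that the cholangiocyte list also holds, was called in 0 of the 8 fits without a library (limma adjusted p 0.0616 to 0.148), and was lost after quantile normalization and with the length trend removed (0.0512 and 0.0536). Kupffer markers were lower in 12 of 12 members beside them (-0.20, camera adjusted p = 0.00781; adjusted p = 0.663 with an estimated correlation), a call lost without fasted control replicate 2, fasted LMKO replicate 1, re-fed control replicate 2 or re-fed LMKO replicate 1 (camera adjusted p = 0.0657, 0.193, 0.221 and 0.0985). Without fasted control replicate 2 the FOXO1-linked median was -0.18, and the periportal median was -0.20 without fasted LMKO replicate 1 and -0.23 without re-fed LMKO replicate 2. The other 7 lists called over both states, cholesterol synthesis, fatty acid synthesis, bile acid genes, interferon-stimulated genes, the proteasome, the cell cycle and stellate markers, each lost the call without at least 1 library. For cholesterol synthesis (median -0.41, camera adjusted p = 3e-05; adjusted p = 0.678 with an estimated correlation) and fatty acid synthesis (-0.33, camera adjusted p = 0.00832; adjusted p = 0.532 with an estimated correlation) that was fasted control replicate 1 (camera adjusted p = 0.134 and 0.0849). Cell cycle genes had a median of -0.13 (camera adjusted p = 0.00759; adjusted p = 0.557 with an estimated correlation), but 0.14 with an FPKM of at least 5, where the direction turned (camera adjusted p = 0.705), and the call was lost without replicate 1 of either control group (0.0971 fasted and 0.06 re-fed). Stellate markers (-0.22, camera adjusted p = 0.0112), interferon-stimulated genes (-0.19, adjusted p = 0.00216) and bile acid genes (-0.12, adjusted p = 0.013) were lower, and proteasome genes (0.16, adjusted p = 0.00216) higher, with an adjusted p = 0.452, 0.683, 0.405 and 0.748 with an estimated correlation. Without fasted LMKO replicate 1 the stellate, interferon and proteasome calls were lost (camera adjusted p = 0.11, 0.331 and 0.111), without re-fed control replicate 2 the stellate, interferon and bile acid calls (0.294, 0.221 and 0.13), and without fasted control replicate 1 the bile acid and proteasome calls (0.134 and 0.186). An FPKM of at least 5 ended the stellate and interferon calls (camera adjusted p = 0.369 and 0.0901), removal of the length trend the stellate and bile acid calls (0.0932 and 0.0533), and quantile normalization the proteasome call (0.0542).

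The other axis of the design asked what re-feeding changed within each genotype. In control liver, Igfbp1 fell from 419.9 ± 288 to 1.32 ± 0.463 FPKM (SD, n = 2; log2 fold change -7.33, SE 0.65, limma adjusted p = 0.00167). The metallothionein genes, whose products bind zinc, fell too: Mt2 from 461.5 ± 159 to 2.28 ± 0.893 FPKM (-7.12, limma adjusted p = 0.000257) and Mt1 from 690 ± 208 to 11.7 ± 0.680 (-5.73, limma adjusted p = 0.000211). Cidec, a lipid droplet protein, fell by 4.94 (limma adjusted p = 0.00633) and Eif4ebp3, a repressor of translation, by 4.50 (adjusted p = 0.00176). Car3, a carbonic anhydrase abundant in fed liver, rose from 57.2 ± 37.1 to 3643 ± 307 FPKM (6.13, SE 0.42, limma adjusted p = 0.00105). Thrsp, an inducer of lipogenesis, rose from 44.6 to 1147 FPKM (4.63, limma adjusted p = 0.00439), Gstm3, a glutathione transferase, from 1.85 to 94.7 FPKM (5.08, adjusted p = 9.79e-05), and Cyp26a1, which degrades retinoic acid, by 4.54 (adjusted p = 0.00167). Hsd3b5, a steroid dehydrogenase of male liver, rose by 4.56 (limma adjusted p = 0.0201) but was not called without fasted control replicate 2, re-fed control replicate 1 or re-fed control replicate 2 (limma adjusted p = 0.0951, 0.0652 and 0.092), nor with no filter on low values or the robust setting of eBayes (0.0503 and 0.0522).

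Re-feeding changed 3610 of 10865 genes in controls, 2473 up and 1137 down (68.5% up). The median log2 fold change of all genes was 0.13 in these values and -0.001 after median-ratio scaling, which split the calls into 1804 up and 1751 down (50.7% up); quantile normalization gave 1672 and 1694 (49.7% up). Both scalings centre the fold changes, so a split near 50% follows from them. The count was 1539 without fasted control replicate 2 and 1773 without re-fed control replicate 2. The list medians below are as deposited and can be set against the median of 0.13.

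Of the 39 lists 13 were called in re-fed against fasted controls. Of 12 gluconeogenesis genes 6 fell, 2 rose and 4 did not pass, and 7 fell and 2 rose when adjusted over the list alone (median -0.81, camera adjusted p = 0.00226; adjusted p = 0.41 with an estimated correlation). Pck1 fell from 2186 to 374 FPKM (-2.54, SE 0.12, limma adjusted p = 0.000328) and Ppargc1a by 1.44 on the log2 scale (adjusted p = 0.00105). The list median was -0.53 without fasted control replicate 2. Of 18 FOXO1-linked genes 10 fell and 1 rose, or 11 and 2 when adjusted over the list alone (-0.76, camera adjusted p = 0.000118; adjusted p = 0.41 with an estimated correlation), and Irs2, an insulin receptor substrate, fell by 2.18 (limma adjusted p = 0.000823). Of 25 genes of fatty acid oxidation and ketogenesis 17 fell and 1 rose, or 20 and 2 when adjusted over the list alone (-1.04, camera adjusted p = 3.72e-10; adjusted p = 0.667 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, fell by 3.67 on the log2 scale. Of 15 lipid droplet genes 7 fell, also 7 when adjusted over the list alone (-0.58, camera adjusted p = 0.00226; adjusted p = 0.667 with an estimated correlation), among them Pnpla2, the triglyceride lipase, by 2.34; the median was -0.90 without re-fed control replicate 1 and -0.36 without re-fed control replicate 2.

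Lipid synthesis genes rose with re-feeding in controls. Of 18 fatty acid synthesis genes 10 rose and 8 did not pass, or 12 rose when adjusted over the list alone (median 1.38, camera adjusted p = 0.00282; adjusted p = 0.667 with an estimated correlation). Srebf1, the transcription factor of lipogenesis, rose from 8.07 to 132 FPKM (4.05, limma adjusted p = 0.00319), and Acly, which makes cytosolic acetyl-CoA, by 2.46. Of 24 cholesterol genes 14 rose and 10 did not pass, or 17 rose when adjusted over the list alone (2.18, camera adjusted p = 0.000241; adjusted p = 0.776 with an estimated correlation), including Sc5d from 40.7 to 297 FPKM (2.93, limma adjusted p = 0.00284). Of 20 chaperones of the endoplasmic reticulum 16 rose, also 16 when adjusted over the list alone (0.95, camera adjusted p = 6.23e-06; adjusted p = 0.667 with an estimated correlation), and Manf rose from 11.7 to 69.9 FPKM (2.48, limma adjusted p = 0.00105). Of 13 cell cycle genes 9 rose, or 10 when adjusted over the list alone (0.95, camera adjusted p = 0.00299; adjusted p = 0.667 with an estimated correlation), including Mcm6, a subunit of the replicative helicase, by 2.06 (limma adjusted p = 0.00757) and Tk1, a thymidine kinase, by 1.75; the median was 0.59 without re-fed control replicate 1. With an FPKM of at least 5 the cell cycle call was lost (median 0.46, camera adjusted p = 0.427). NRF2-linked genes, which respond to oxidative stress, rose in 6 of 14, also 6 when adjusted over the list alone (0.77, camera adjusted p = 0.0102; adjusted p = 0.667 with an estimated correlation), with Gclc, of glutathione synthesis, up by 1.17; with an FPKM of at least 5 this call was lost (camera adjusted p = 0.0576).

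Of 48 ribosomal protein genes 44 rose in re-fed controls, also 44 with 1 fall when adjusted over the list alone (median 0.71, camera adjusted p = 3.72e-10; adjusted p = 0.667 with an estimated correlation). Rpl35 rose from 220 to 446.5 FPKM (1.02, limma adjusted p = 0.00344). Of 45 oxidative phosphorylation genes 31 rose, or 35 when adjusted over the list alone (0.47, camera adjusted p = 4.7e-07; adjusted p = 0.667 with an estimated correlation), with Ndufs8 up by 0.96 (limma adjusted p = 0.0024). Of 31 proteasome genes 12 rose, or 13 when adjusted over the list alone (0.34, camera adjusted p = 0.0113; adjusted p = 0.83 with an estimated correlation), with Psmb5 up by 0.99. These lists, with many short transcripts, moved with the relation of the deviations to transcript length, which differed between fasted and re-fed libraries. With the length trend removed the ribosomal median was 0.37, and the proteasome list was at 0.09 and no longer called (camera adjusted p = 0.277). After quantile normalization the ribosomal median was 0.34, that of oxidative phosphorylation 0.07 with the call lost (camera adjusted p = 0.15) and that of the proteasome -0.03 (camera adjusted p = 0.77). The proteasome call was also lost without fasted control replicate 1 (camera adjusted p = 0.209) and with an FPKM of at least 5 (0.0556). Sinusoidal endothelial markers fell in 6 of 12 members, also 6 when adjusted over the list alone (-0.56, camera adjusted p = 0.00282; adjusted p = 0.667 with an estimated correlation), with Stab2, a scavenger receptor, from 9.79 to 4.71 FPKM (-0.92, limma adjusted p = 0.00897, and 0.0507 without fasted control replicate 2), while Kupffer markers were not called (-0.13, camera adjusted p = 0.223).

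**Figure D2:**
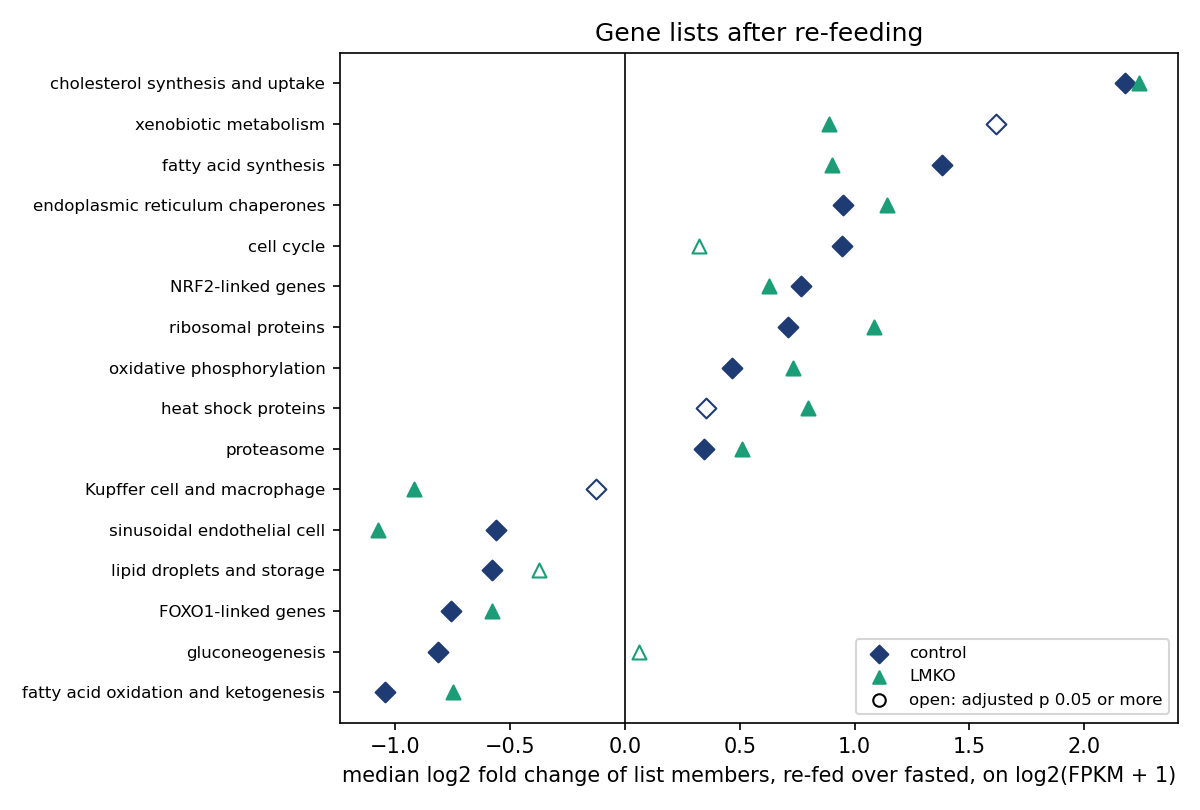
Median log2 fold change (log2 of FPKM + 1, re-fed over fasted) of the gene lists called in either genotype, control beside LMKO; filled points had a camera adjusted p under 0.05 and open points 0.05 or more. Cholesterol genes lie at 2.18 and 2.24 and gluconeogenesis genes at -0.81 in control and 0.06 in LMKO liver, the last at -0.03 after median-ratio scaling and -0.41 after quantile normalization.

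In LMKO liver re-feeding changed 4296 of 10865 genes, 2521 up and 1775 down (58.7% up), against 2222 and 2211 after median-ratio scaling (50.1% up) and 2012 and 2014 after quantile normalization (50% up). Mt2 fell from 427 to 2.59 FPKM (-6.89, limma adjusted p = 0.000361), Mt1 from 719 to 20.0 (-5.10, adjusted p = 0.000361) and Igfbp1 from 46.9 to 0.860 (-4.50, limma adjusted p = 0.00356). Lepr, the leptin receptor, fell by 3.30 on the log2 scale (limma adjusted p = 0.0102), but was not called without fasted LMKO replicate 1 or re-fed LMKO replicate 1 (limma adjusted p = 0.0555 and 0.0506). Selenbp2 rose from 2.32 to 106.8 FPKM (5.03, limma adjusted p = 0.00206), Thrsp from 36.4 to 719.7 (4.57, adjusted p = 0.00331), Gstm3 by 4.71 (adjusted p = 0.000107) and Fdps, of the isoprenoid pathway, from 18.9 to 429.8 FPKM (4.34, limma adjusted p = 0.00652). The count was 2683 and 2311 without fasted LMKO replicate 1 and 2, and 2291 and 2193 without re-fed LMKO replicate 1 and 2.

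Again 13 of the 39 lists were called in LMKO, all but 1 with an adjusted p = 0.634 with an estimated correlation. The exception was the proteasome at 0.661 with an estimated correlation. Pck1 fell from 839 to 215 FPKM (-1.96, SE 0.12, limma adjusted p = 0.000734) and Irs2 by 2.03. Of 12 gluconeogenesis genes 3 rose, 3 fell and 6 did not pass, and this list was not called (median 0.06 with camera's direction down, adjusted p = 0.576). Its median was -0.03 after median-ratio scaling, -0.41 after quantile normalization and -0.12 with the length trend removed, also not called (camera adjusted p = 0.649, 0.0961 and 0.49). FOXO1-linked genes fell in 8 of 18 members and rose in 1, the same counts as when adjusted over the list alone (-0.58, camera adjusted p = 0.00385). Genes of fatty acid oxidation and ketogenesis fell in 14 of 25, or 15 with 1 rise when adjusted over the list alone (-0.75, camera adjusted p = 1.1e-05), with Vnn1, a pantetheinase, at -3.18. Cholesterol genes rose in 17 of 24, also 17 when adjusted over the list alone (2.24, camera adjusted p = 4.84e-05), with Dhcr7 up by 2.46 (limma adjusted p = 0.0025). Fatty acid synthesis genes rose in 9 of 18, also 9 when adjusted over the list alone (0.90, camera adjusted p = 0.0372), with Fasn up by 2.65 (limma adjusted p = 0.00369). That call was lost without re-fed control replicate 1, re-fed control replicate 2 or re-fed LMKO replicate 1 (camera adjusted p = 0.053, 0.053 and 0.0897), after quantile normalization (0.108) and with an FPKM of at least 5 (0.109).

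Chaperones of the endoplasmic reticulum rose in 16 of 20 (median 1.14, camera adjusted p = 6.05e-06), also 16 when adjusted over the list alone, with Hspa5, their main member, up by 1.70. Heat shock proteins rose in 11 of 16, or 13 when adjusted over the list alone (0.80, camera adjusted p = 0.000338), with Bag3 up from 7.84 to 27.6 FPKM (1.70, limma adjusted p = 0.000843). Ribosomal protein genes rose in 47 of 48 (1.08, camera adjusted p = 2.52e-16), oxidative phosphorylation genes in 41 of 45 (0.73, adjusted p = 1.85e-11) and proteasome genes in 15 of 31 (0.51, adjusted p = 0.000121), or 47, 41 and 16 when adjusted over the list alone. With the length trend removed the ribosomal median was 0.70, and after quantile normalization 0.51. The proteasome call was lost after quantile normalization (camera adjusted p = 0.242), and its median was 0.32 without fasted LMKO replicate 2. Genes of xenobiotic metabolism rose in 12 of 26 and fell in 3, or 12 and 4 when adjusted over the list alone (0.89, camera adjusted p = 0.0466), with Gstm2, a glutathione transferase, up by 3.08. This call was lost after quantile normalization (0.178) and with an FPKM of at least 5 (0.181), and the median was 1.36 without re-fed LMKO replicate 2. In control liver the xenobiotic list had a larger median (1.62) and was not called in the deposited values. It was called there after median-ratio scaling, quantile normalization and removal of the length trend (camera adjusted p = 0.00784, 0.0299 and 0.00902). NRF2-linked genes rose in 5 of 14, also 5 when adjusted over the list alone (0.63, camera adjusted p = 0.0285); the median was 1.13 without fasted LMKO replicate 1, 0.40 without re-fed LMKO replicate 2 and 0.18 without fasted LMKO replicate 2, where the call was lost (camera adjusted p = 0.0696). It was also lost after quantile normalization (camera adjusted p = 0.0972) and with an FPKM of at least 5 (0.111). Markers of other cells moved beside these groups. Sinusoidal endothelial markers fell in 9 of 12, or 10 when adjusted over the list alone (-1.08, camera adjusted p = 1.2e-05), with Kdr from 13.6 to 3.18 FPKM (-1.81, limma adjusted p = 0.00163). Kupffer markers fell in 7 of 12, also 7 when adjusted over the list alone (-0.92, camera adjusted p = 0.00144), with Csf1r from 11.4 to 3.26 FPKM (-1.54, limma adjusted p = 0.0037).

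Whether re-feeding acted differently in the genotypes was tested by the interaction. It called 4 genes, Mir1898, Mir215, Mir5123 and Snord23, all of which span under 200 bases, with 1016 genes at an unadjusted limma p under 0.05; without such loci it called 0. As in the genotype comparisons, the p-values of these loci are not read as a difference. The count was 16 without fasted control replicate 1, 7 without fasted control replicate 2 or fasted LMKO replicate 2, and 8 without either re-fed control. At the level of lists, 14 of 39 had a called interaction. Fatty acid synthesis (median -0.31) was not among them. It was called after median-ratio scaling, quantile normalization and removal of the length trend (camera adjusted p = 0.0498, 0.0197 and 0.0352). Clock genes (-0.58), also not among them, were called after median-ratio scaling and removal of the length trend (0.0443 and 0.0464) but not after quantile normalization (0.0512). Gluconeogenesis genes had a positive interaction in all 12 members, 4 of them called when adjusted over the list alone (median 0.47, camera adjusted p = 2.92e-07; adjusted p = 0.167 with an estimated correlation). Tat had an interaction of 1.79 (limma adjusted p = 0.481), Got1 of 1.33 (adjusted p = 0.451) and Pck1 of 0.59 (adjusted p = 0.507). Heat shock proteins had a positive interaction in 15 of 16 members, 2 of them called when adjusted over the list alone (0.52, camera adjusted p = 6.69e-08; adjusted p = 0.448 with an estimated correlation), with Hspa8 at 1.29, and ribosomal protein genes in 48 of 48 (0.35, camera adjusted p = 1.11e-16; adjusted p = 0.48 with an estimated correlation). Cell cycle genes (-0.63, camera adjusted p = 7.8e-05) and sinusoidal (-0.60, adjusted p = 2.45e-05) and Kupffer markers (-0.72, adjusted p = 0.00114) had a negative interaction in every measured member, with an adjusted p = 0.448, 0.48 and 0.585 with an estimated correlation. The cell cycle median was -0.42 without re-fed LMKO replicate 1, and with an FPKM of at least 5 it was -0.25 and the call was lost (camera adjusted p = 0.155).

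**Figure D3:**
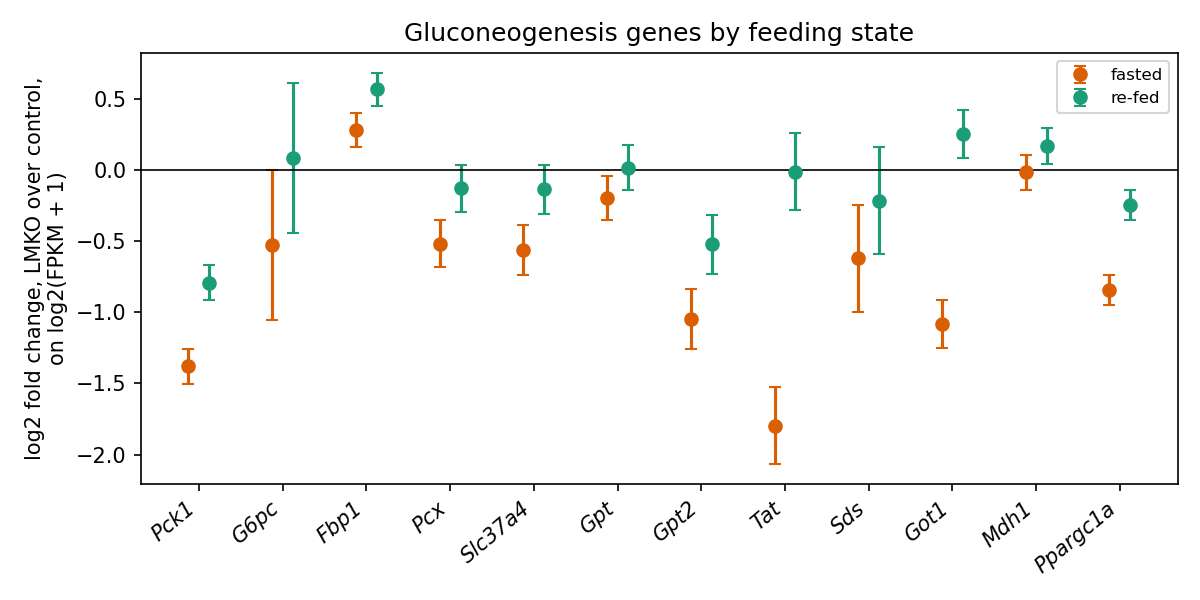
Log2 fold change (log2 of FPKM + 1, LMKO over control) of the 12 gluconeogenesis genes in the fasted and the re-fed state; points are limma estimates from 2 libraries per group and bars are SE. In the fasted state Pck1 lies at -1.38 and the list median at -0.59, and in the re-fed state at -0.79 and -0.07.

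The genotype calls of both feeding states shared 5 falls (Mup7, Mup11, Mup12, Mup16 and Mup17), where independent lists would share 0.0118, and 1 rise (Snora2b), where they would share 0.000552. The 2 comparisons have no library in common, but the spread of each gene was estimated once from all 8 libraries for both. The 5 falls are Mup copies that share reads, and Snora2b spans under 200 bases and is not read as a difference. The numbers for independent lists are therefore no fair expectation for these calls. With only the 4 libraries of each comparison, 2 calls were shared. Across genes the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.245 and a Spearman correlation of 0.147. Genes are not independent replicates. The re-feeding calls of control and LMKO liver shared 1857 rises (574 for independent lists) and 850 falls (186), while 1 gene that rose and 4 that fell in controls were called the other way in LMKO. The count of 6 shared genotype calls was 2 without re-fed control replicate 2 or re-fed LMKO replicate 2.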

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

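The split of the libraries was chosen before the result was seen. The tests of transcript length were added after the data were seen, with their bounds set before the values with the length trend removed were known, and the test of transcript length in LMKO liver alone and the other tests of explanations in this part were chosen after the result was seen.

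Each result in this paragraph and the next stands out because the interaction of genotype and re-feeding passed its test. The genes were Mir1898 (limma adjusted p = 1.26e-06), Mir5123 (1.26e-06), Mir215 (6.68e-05) and Snord23 (0.00526), and each was listed at 0 in all groups but 1. In that group the FPKM of replicate 1 over replicate 2 was 0.925 for Mir1898, 1.041 for Mir215 and 1.041 for Mir5123, and the relative depth of replicate 2 over replicate 1 was 0.925, 1.04 and 1.04, so the library of higher depth had the lower FPKM. For Snord23 these ratios were 0.508 and 1.017. Equal or doubled fragment numbers would give such ratios, so the p-values of these 4 loci are not read as a difference between groups. Snord23 was not called without re-fed LMKO replicate 1 or 2 (limma adjusted p = 0.052 and 0.0519).

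Lists with a positive interaction (camera adjusted p) were ribosomal proteins (1.11e-16), oxidative phosphorylation (2.69e-08), heat shock proteins (6.69e-08), gluconeogenesis (2.92e-07), the urea cycle (0.000164), the proteasome (0.00292), fatty acid oxidation (0.00404), lipid droplets (0.00433), FOXO1-linked genes (0.0128) and immediate-early genes (0.0241). Those with a negative interaction were sinusoidal endothelial (2.45e-05), Kupffer (0.00114) and stellate markers (0.00447) and the cell cycle (7.8e-05). With an estimated correlation the smallest adjusted p among them was 0.167, for gluconeogenesis. Calls were lost for the proteasome without replicate 2 of either fasted group (camera adjusted p = 0.239 for control and 0.401 for LMKO), for fatty acid oxidation without fasted control replicate 2 (0.387), for lipid droplets without re-fed control replicate 2 (0.0694), for FOXO1-linked genes without re-fed LMKO replicate 1 (0.0646) and for stellate markers without fasted LMKO replicate 2 (0.0621) or re-fed control replicate 2 (0.219). Immediate-early genes were not called without fasted control replicate 2, fasted LMKO replicate 1, re-fed control replicate 1 or re-fed LMKO replicate 1 (camera adjusted p = 0.332, 0.132, 0.227 and 0.0646). Quantile normalization kept 9 of the 14 and lost oxidative phosphorylation (camera adjusted p = 0.104), FOXO1-linked genes (0.104), the urea cycle (0.341, median 0.09), fatty acid oxidation (0.341) and the proteasome (0.127). An FPKM of at least 5 kept 10 and lost the cell cycle (0.155), stellate markers (0.202), immediate-early genes (0.239) and FOXO1-linked genes (0.0583). Immediate-early genes were also lost after median-ratio scaling and with the length trend removed (camera adjusted p = 0.0668 and 0.0641).

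The lower Mup values in LMKO liver were weighed first. Reads moved between near-identical copies would leave the family sum alone, but the highest LMKO sum was 0.557 of the lowest control sum of the same feeding state, taking the larger of both states. A strain variant in the central copies may lower their FPKM. The 5 Mup genes outside them had a median log2 fold change of -0.9801 over both states. Of these, 4 were lower in both states, 1 (Mup5) was called, and Mup20 was at 0.37 after re-feeding. As Mup copies can share reads, these are no separate check. The falls of Mup7 and Mup17 were far larger (-6.97 and -7.67 over both states), and a central variant stays open. Mup10, which lies between Mup7 and Mup17 on chr4, was at -0.76 over both states and not called (limma adjusted p = 0.1725). A lower male-biased expression in LMKO liver stays open: without its Mup members that list had a camera p of 2.14e-05, but a p of 0.0875 with an estimated correlation, and 8 of 14 members were lower in both states. The labels give C57/BL6 for all mice, but the strain in which the deletion was made is not given in the sources used here, so a variant that acts on the whole family also stays open.

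The higher ribosomal protein genes were weighed next, since deviations from the mean over all libraries fell with transcript length in 3 of the 4 re-fed libraries and rose with it in the fasted ones. Between re-fed LMKO and control the median of 0.45 was 0.334 without the length trend, which argues against length as the whole cause. The lower of the 2 scalings gave 0.2585, near the length bound of 0.2252, so normalization stays open. Both were called. After re-feeding the median without the length trend was 0.6962 in LMKO (1.0833 with it) and 0.3682 in control (0.7118 with it). Both were called (camera adjusted p = 2.93e-14 and 2.21e-07). The share kept was 0.643 and 0.517 where a bound of 0.5 had been set, which argues against length as the whole cause in LMKO, but in control liver the median lay above that bound by 0.01 with an SE of 0.05, so length stays open there. A batch between fasted and re-fed libraries also stays open, since 0 name prefixes occurred in both states and it cannot be told apart from feeding, and a response of ribosomal protein genes to Med23 loss remains an untested biological explanation.

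Genes that flank a deleted locus can carry variants of the strain in which the deletion was made, so genes within 10 Mb of Med23 were looked at last. Of the 100 loci with the smallest p over both states, 3 lay among the 55 tested loci of that region (Fisher's exact p = 0.014). These were Raet1b, Raet1c and Raet1d at -1.26, -1.05 and -0.78 (limma adjusted p = 0.0835, 0.0862 and 0.0707). They share reads, so they are not 3 separate hits for that test, and lay at or below 1.24 FPKM when fasted. Without the Raet1 loci 0 of 51 were among those 100, against 0.47 by chance (limma gave 1646 genes an unadjusted p under 0.05). A flanking variant may still act on the Raet1 genes alone, and too few loci lie in the region to tell.

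For the 34 genes changed by genotype over both states, the 8 libraries were split in 35 ways with feeding state as a term where it could enter, and the real split called 17 genes in that fit. Of the 35 splits 2 called as many, the real one included. The other was the split by feeding state with 5403 genes, which is a structure of the samples and was fitted without the feeding term. With that split among the 35 a share under 0.05 cannot be reached, so their count decides nothing. Of the 34 splits fitted with the feeding term, the real one called 17 genes and each other at most 3.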

How the results depend on the processing

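The fits without loci under 200 bases and with the length trend removed were chosen after the result was seen; the other alternatives were planned. For the called genes and lists with alternatives, fold changes kept their direction in each one run except for the list medians named here; uncalled lists were run only under the scalings and without the length trend, and genes that did not pass were not, except Med23. The count of genes changed by genotype after fasting, 18, became 11 with no filter on low values, 8 with only the 4 libraries of the comparison, 53 at an adjusted p under 0.1 and 12 to 57 without 1 library. After re-feeding the count of 11 became 14 with only the 4 libraries, 17 at an adjusted p under 0.1, 7 without loci under 200 bases, and 5 to 14 without 1 library. Over both states 34 became 117 at an adjusted p under 0.1 and 18 to 55 without 1 library. The shared genotype calls, 6, became 3 with no filter, 2 with only the 4 libraries of each comparison, and 2 to 9 without 1 library. Re-feeding changed 3610 genes in controls, 1968 with only the 4 libraries and 1539 to 3151 without 1 library, and 4296 in LMKO, 4278 with only the 4 libraries and 2193 to 4251 without 1 library. The interaction count of 4 became 7 with no filter, 0 without loci under 200 bases (limma; 1016 at an unadjusted p under 0.05 with them) and 3 to 16 without 1 library. Among the fits without 1 library, the highest counts of the fasted genotype, both states and the interaction, 57, 55 and 16, came without fasted control replicate 1. The cause of these changes was not tested. Med23 was lower in LMKO and not called in each alternative run for it; an FPKM of at least 5 removes it, so that one gives no value.

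With the replicate block, a fit in which libraries with the same replicate number share a term, 13 genes were called by genotype after fasting, 10 after re-feeding, 2967 and 3804 by re-feeding in control and LMKO, 4 for the interaction and 18 over both states, with 7 shared. Same-numbered libraries did not deviate together (correlations of deviations between groups -0.084 to -0.008). These values gave no sign that the numbers pair the samples, but they cannot exclude a pairing with small effects.

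Of the 10, 17, 13, 13, 14 and 16 lists called in the fasted and re-fed genotype, the control and LMKO re-feeding, the interaction and the both-state genotype comparisons, 0 were kept with camera's estimated correlation, 2, 0, 10, 11, 1 and 2 were kept with fry, and 9, 15, 10, 10, 10 and 13 with an FPKM of at least 5. Quantile normalization kept 9, 17, 11, 9, 9 and 15. Direction turned for cholesterol synthesis and uptake between the fasted genotypes, from a median of -0.5534 to 0.0922 without fasted control replicate 1 (camera adjusted p = 0.972) and -1.0512 without fasted control replicate 2, and for the cell cycle over both states, from -0.1333 to 0.1363 with an FPKM of at least 5 (camera adjusted p = 0.705). The medians, but not the direction of the test, also changed sign for the proteasome after re-feeding of controls (quantile normalization, -0.03), cholesterol genes in the re-fed genotypes (0.05, without re-fed LMKO replicate 1), immediate-early genes in the fasted genotypes (0.04, without fasted control replicate 2) and the fatty acid oxidation interaction (-0.05, without fasted control replicate 2). The cause was not tested. Fragment depth is unknown, which limits low FPKM values and loci under 200 bases most.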

Other observations

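The values in this part were looked at after the report's results were seen, except for the gene lists, which were fixed in advance.

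The other subunits of Mediator did not move with Med23 as a list: of 31 measured members 23 were higher in fasted LMKO (median log2 fold change 0.09, camera adjusted p = 0.726) and 20 in re-fed LMKO (0.05, camera adjusted p = 0.236). With an estimated correlation the adjusted p was 0.989 and 0.697. Hepatocyte markers had a median of 0.05 between the fasted genotypes (camera adjusted p = 0.933), which was -0.04 after median-ratio scaling, and 0.14 between the re-fed genotypes (0.338), which was -0.11 after quantile normalization. Female-biased liver genes had 7 of 10 members higher in fasted LMKO (0.36, camera adjusted p = 0.985) and 5 of 10 in re-fed LMKO (-0.07, adjusted p = 0.941), and camera's direction was opposite in sign to the median in both. Glycolysis genes rose with re-feeding in 7 of 16 members and fell in 2 in controls (7 and 2 when adjusted over the list alone), and rose in 6 and fell in 1 in LMKO (7 and 1 over the list alone), without a list call (camera adjusted p = 0.311 and 0.121). Acute phase proteins, which the liver secretes in inflammation, were not called in either genotype comparison (camera adjusted p = 0.933 and 0.395).

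Ctcfl, 1300015D01Rik and Pck1, which all fell in fasted LMKO liver, lie close together on chr2, between 172919110 and 172984754 (mm9), with log2 fold changes of -1.35, -2.03 and -1.38. They were singled out after their values were seen.

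Alb was listed at 0 in all 8 libraries, while Apoa2, another abundant hepatocyte transcript, ranged from 4581 FPKM in fasted control replicate 2 to 19333 FPKM in re-fed LMKO replicate 1.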
